A study of Mus musculus with 8 samples.

How the data were processed

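GFP-positive cells were sorted by FACS from digested kidneys of FSP1-GFP mice on a C57BL/6 background, per the labels' protocols. Total RNA was isolated with the Qiagen miRNeasy kit, amplified with NuGEN WT-Ovation Pico, biotin-labelled with NuGEN FL-Ovation and hybridised to Affymetrix mouse arrays, per the labels' protocols and the series' design text. The authors deposited 1 table of probe set intensities on a linear scale for 8 arrays, with a floor near 1. The software, background correction, summary method and scaling behind these intensities are not given in the sources used here. Such amplification of small RNA amounts can add spread between arrays, which was not tested here, and the number of arrays limits the precision. Groups came from the sample titles, with 5 ischemic and 3 normal arrays.

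Intensities were taken as log2(value + 16), so that a value of 1 becomes 4.09. The quartiles of the arrays differed by 0.28, 0.30 and 0.39 (lower, median, upper), above the tolerance of 0.1, so arrays were quantile normalized. Of 45101 probe sets, 64 controls were left out of the tests, 34945 had 1 gene symbol in the annotation given with the series, 932 had several and 9160 were not listed there. Only probe sets with 1 symbol were named. Of their symbols, 34741 matched a RefSeq gene ID (table of assembly GRCm38.p6, used for names only) and 204 did not, and 0 symbols changed. A gene was represented by its probe set with the highest mean over the 8 arrays, which gave 18193 genes, with no filter on brightness. Different probe sets of a gene can disagree, and the closing part gives results with other rules. No coordinates are given, since no genome build is named for the array.

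Ischemic and normal arrays were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Gene lists for 40 cell types and processes, with 721 genes of which 663 were measured, were tested with limma camera at a preset correlation of 0.01, adjusted over the 40 lists. The same lists were tested with an estimated correlation, with limma's fry and by a two-sided exact permutation test of the list mean per array over all 56 splits, whose smallest p is 0.0179. These permutation p values of list means are not adjusted, and adjusted over the 40 lists the lowest is 0.179. Array quality was compared with the same exact test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

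The groups, tests, lists, main settings and most alternatives were set before the data were examined. The rule for named genes took S100a4 and, in each direction, the 12 genes with the largest change among those past the threshold with groups apart and a mean in the higher group at or above the median of all genes. Where fewer passed, the genes of lowest unadjusted p filled the 12 and are said not to have passed, which here was all of them. For each list described, up to 4 members past the threshold over all genes were to be named, or, where none passed, the 2 with the highest mean level. Members named for passing adjusted over the list alone (up to 4 per list, by size of change, with Slc4a1) were chosen after their values were seen, as were Xist, the Y-linked genes and the use of Xist signal to divide the arrays.

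Alternatives were the replicate number as a block, centring of arrays on the median or on ribosomal protein genes in place of quantile normalization, pseudocounts of 1 and 64, keeping genes above the 40th or 60th percentile of brightness, other rules for probe sets, eBayes with trend or robust, array weights, other thresholds and leaving out each array. The quality measures were only recomputed with each array left out. Camera has no robust setting, so lists were not run under it. The limma step was tested on simulated data with the means of the 18193 genes, their spreads as moderated by limma, and 200 changed genes in 20 draws. The changed genes were drawn from those above the median level, and all genes varied independently. The limma step recovered 3.5% of 2-fold, 45.9% of 4-fold, 82.2% of 8-fold and 94.4% of 16-fold changes, with 4.44% false among the calls. These rates do not cover changes of dim genes or genes that vary together. They also need not hold for the measured genes, where Slc34a1 at 14.7-fold and Nat8 at 11.3-fold did not pass. The count of genes passing thus does not show how many such changes exist. Camera called 20 of 20 shifted lists and 0 of 780 unshifted ones on simulated arrays with independent genes, which does not test lists whose genes vary together.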

Results

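Gene expression was measured with Affymetrix mouse arrays in GFP-positive cells sorted from the kidneys of mice in which GFP is driven by the FSP1 (S100a4) promoter, a reporter often used to mark fibroblasts. The ischemic group held 5 kidneys taken 3 days after the left renal artery and vein had been clamped for 45 minutes and released. The control group held 3 kidneys, which the labels call both normal and sham. Mice were 6 months old, and the labels describe the samples as separate kidneys, with 5 mice in the ischemic group. The comparison asks how the sorted cells differ between a kidney in acute injury and a kidney without it. The number of arrays, 5 against 3, limits the precision of every value below, and differences are on the log2(intensity + 16) scale, which understates the change of dim genes.

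S100a4, whose promoter drives the reporter, was bright in both groups, at 11.97 ± 0.27 (SD, n = 5) in ischemic and 11.61 ± 0.32 (SD, n = 3) in normal arrays. The difference of 0.37 ± 0.25 (SE) did not pass limma (adjusted p = 0.893) or a two-sided exact permutation test over the 56 splits of the 8 arrays (p = 0.143), and the difference was 0.21 without normal replicate 1 and 0.19 with arrays centred on ribosomal protein genes. The 3'-to-5' difference of the Gapdh control probe sets, a measure of RNA integrity, was 2.42 ± 0.27 (SD, n = 5) in ischemic and 2.23 ± 0.19 (SD, n = 3) in normal arrays (exact permutation p = 0.321). For beta-actin the values were 0.14 ± 0.32 (SD, n = 5) and −0.10 ± 0.09 (SD, n = 3; exact permutation p = 0.304). Neither the array median (exact p = 0.875) nor the interquartile range (exact p = 0.339) passed the test. With 1 array left out none of the 4 differences passed, but their sizes moved. Ischemic minus normal, Gapdh went from 0.19 to 0.11 without normal 1, to 0.12 without ischemic 3 and to 0.30 without normal 2 or ischemic 2, and beta-actin from 0.24 to 0.12 without ischemic 3. The interquartile range went from −0.16 to −0.058 without ischemic 1, and the array median from −0.015 to −0.056 without ischemic 1, −0.054 without normal 2, −0.033 without normal 1 and −0.032 without ischemic 5. The array median turned to 0.0058 without ischemic 2, 0.019 without ischemic 4 and 0.043 without normal 3. Ischemic 1 stood apart, with a median correlation of 0.753 with the other arrays across genes. The other 4 ischemic arrays lay between 0.890 and 0.903. The highest correlation of any pair, 0.976, joined ischemic 5 and normal 3, which belong to different groups. Normal 3 was also closer to ischemic 3 (0.950) than to either other normal array (0.891 and 0.923). The main axis of variation (37.0% of the variance) did not differ by the test between the groups (exact permutation p = 0.339). It mainly set ischemic 1 (−134) apart from the other arrays (−16.8 to 37.7). The next axis (22.7%) had an exact permutation p of 0.0357, but the groups overlapped on it, with normal 3 at −3.22 and ischemic 1 at 8.83. The axis after it had an exact permutation p of 0.607, and these p values are not adjusted.

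No single gene passed the threshold over all genes tested, and those of lowest p included macrophage, cell cycle and kidney genes. Among the 12 with the lowest p on the higher side were Mrc1, the macrophage mannose receptor, at 2.08 ± 0.31 (SE, n = 5 and 3), and Cx3cr1, the fractalkine receptor of monocytes and macrophages, at 1.77 ± 0.40. With them were Fcrls, a macrophage and microglia gene, at 3.13 ± 0.58, and Ccl8, a chemokine, at 1.89 ± 0.40. Cdt1, which licenses replication origins, differed by 2.04 ± 0.45. Prc1, which acts in cytokinesis, differed by 1.64 ± 0.38 and Ube2c, which acts in mitotic exit, by 2.03 ± 0.47. The 12 with the lowest p on the lower side included Sugct at −3.39 ± 0.34 and Slc22a30, an organic anion transporter family member, at −2.23 ± 0.24. Also among them were Nat8 at −3.50 ± 0.44 and Kng1, which encodes kininogen, at −2.89 ± 0.40. Ppargc1a, the coactivator of mitochondrial biogenesis, differed by −3.24 ± 0.46. Sod3, the extracellular superoxide dismutase, differed by −3.18 ± 0.40 and Dnase1 by −3.22 ± 0.44. Some values depended on the scale or the probe sets. With a pseudocount of 64 Ccl8 was at 0.89, Prc1 at 0.82, Fcrls at 1.96, Ube2c at 1.33, Sugct at −1.97 and Slc22a30 at −1.11, and with the mean of all probe sets of a gene Cdt1 was at 0.90, Sod3 at −1.82 and Ppargc1a at −1.79.

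The remaining genes named by the rule were Pprc1, Slfn1, Tnfrsf13b, Plcl2 and Wdfy4 on the higher side, and Wfdc15b, Tmigd1, Grb7, Proc and Tfcp2l1 on the lower side. All 24 had every ischemic array on one side of every normal array, and none passed. The 12 on the higher side spanned 1.07 to 3.13 (limma adjusted p from 0.122 to 0.199). The 12 on the lower side spanned −3.50 to −2.03 (limma adjusted p from 0.0561 to 0.122). Of 18193 genes tested with limma, 0 passed an adjusted p of 0.05, while 1297 had an unadjusted p under 0.05 (384 higher and 913 lower), where chance alone gives about 910. Without normal replicate 1 that count was 808. With limma's intensity trend 31 genes passed, with array weights 5, and with robust variances 0. Without normal replicate 3 there were 113, of which 8 were higher and 105 lower. The groups did not overlap in 969 genes (5.33% of those tested, where chance gives 3.57%), of which 344 were higher and 625 lower. The split of 384 against 913 became 234 against 1011 with arrays centred on their medians in place of quantile normalization, and 141 against 1419 with arrays centred on ribosomal protein genes in its place. That last scaling moved the median of all genes from 0.041 to −0.074, so values under it are read relative to this shift, and it called 216 genes, 3 higher and 213 lower.

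**Figure D1:**
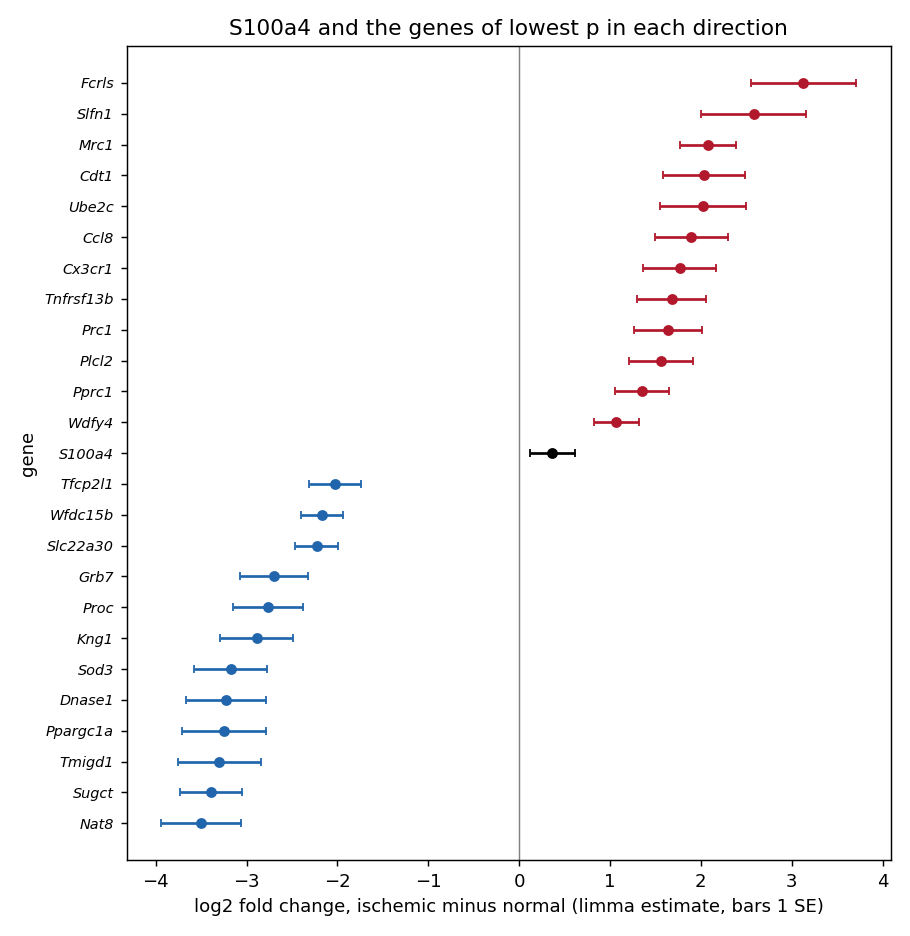
Log2 fold change (ischemic minus normal, limma estimate with bars of 1 SE, 5 against 3 arrays) for S100a4 and the 12 genes of lowest p in each direction, none of which passed the threshold over all genes. Values run from −3.50 for Nat8 to 3.13 for Fcrls, with S100a4 at 0.37.

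Transcripts of the kidney tubule were lower in the cells from ischemic kidneys. The proximal tubule list had a median of −3.29 over its 21 measured members, all of them negative. Its mean per array was 6.98 ± 0.75 (SD, n = 5) in ischemic and 9.86 ± 0.85 (SD, n = 3) in normal arrays. Adjusted over the list alone, 19 members fell, against 0 over all genes tested. They included Slc34a1, the sodium phosphate cotransporter, which fell by 3.88 ± 0.97 (SE), and Lrp2, the endocytic receptor megalin, which fell by 3.87 ± 0.71. They also included Slc22a6, an organic anion transporter, which fell by 3.81 ± 0.71, and Keg1, which fell by 3.70 ± 0.92. Of the brightest members, Pck1, an enzyme of gluconeogenesis, fell by 2.25 ± 0.43 over the list alone. Aqp1, a water channel, differed by −0.51 ± 0.45 and did not pass (−0.82 without normal replicate 1). The list passed limma camera (adjusted p = 2.0e-28) and not with an estimated correlation (adjusted p = 0.157 with an estimated correlation). Its mean per array reached the smallest p of the exact permutation test (0.0179).

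The distal nephron and collecting duct list had a median of −1.50, with all 17 measured members negative and 10 fallen when adjusted over the list alone (0 over all genes tested). Adjusted over the list alone, Egf, the epidermal growth factor precursor of the distal tubule, fell by 3.03 ± 0.59 (SE) and Slc12a1, the cotransporter of the thick ascending limb, fell by 2.84 ± 0.56. Hsd11b2 fell by 2.70 ± 0.61, Pvalb fell by 2.59 ± 0.48 and Umod, which encodes uromodulin, fell by 1.87 ± 0.33 in the same adjustment. Over all alternative settings Slc12a1 ran from −3.50 to −1.48. Wnk1, a kinase also expressed widely, differed by −0.079 ± 0.24 and did not pass, with −0.19 without normal replicate 3 and 0.016 without normal replicate 2. The list mean per array was 6.41 ± 0.25 (SD, n = 5) in ischemic and 7.93 ± 0.10 (SD, n = 3) in normal arrays, at the smallest p of the exact permutation test (0.0179). This was the only list of 40 whose limma camera call (adjusted p = 1.4e-14) held with an estimated correlation (adjusted p = 0.0118 with an estimated correlation). With the proximal tubule list (adjusted p = 0.0350) it was 1 of 2 called by limma's fry (adjusted p = 0.00197), which tests movement in one direction and not against other genes. Its median was −2.26 among genes above the 60th percentile of brightness.

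**Figure D2:**
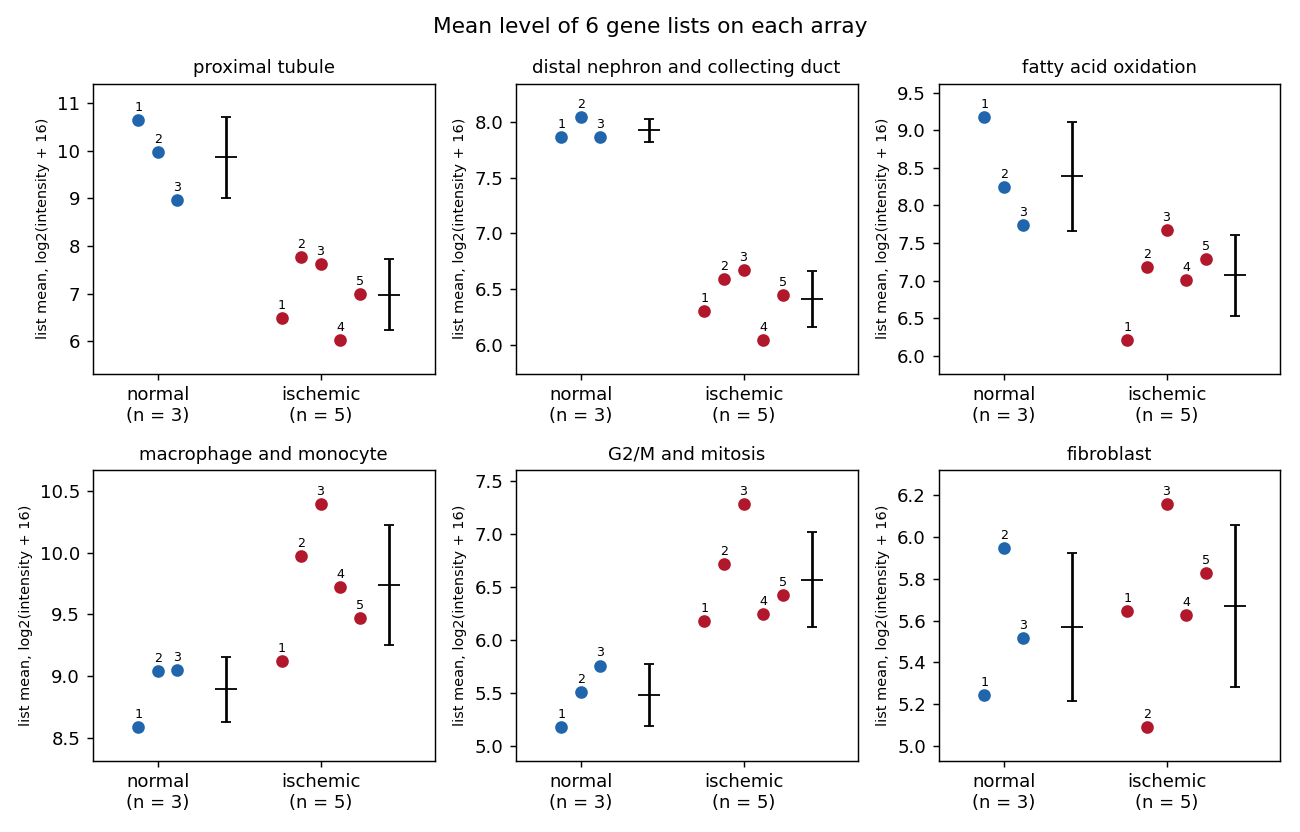
Mean log2(intensity + 16) of the members of 6 gene lists on each array (blue, normal, n = 3; red, ischemic, n = 5; numbers are replicate numbers; black bars are group mean ± SD, and vertical axes do not start at 0). The groups do not overlap for the proximal tubule, distal nephron, fatty acid oxidation, macrophage and G2/M lists, and they do for the fibroblast list.

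The lists of fatty acid oxidation and oxidative phosphorylation genes had negative medians and passed limma camera (adjusted p = 4.1e-11 and 1.2e-12). Neither passed with an estimated correlation (adjusted p = 0.348 for both with an estimated correlation) or with limma's fry (adjusted p = 0.189 and 0.185). The fatty acid oxidation list had a median of −1.14, with 18 of 19 measured members negative and 5 fallen when adjusted over the list alone (0 over all genes tested), among them Ppargc1a. In the same adjustment Ehhadh, a peroxisomal enzyme, fell by 2.53 ± 0.58 (SE), Hadh fell by 2.16 ± 0.56 and Decr1 fell by 1.88 ± 0.54, the last with a value of −1.23 without normal replicate 1. Hadha, of the mitochondrial trifunctional protein, differed by −1.14 ± 0.48 and did not pass. The oxidative phosphorylation list had a median of −0.65 with all 24 members negative and 0 past the threshold adjusted over the list alone or over all genes tested. Cox6c was at −0.71 ± 0.19 and Atp5a1 at −0.57 ± 0.24. The means per array gave exact permutation p values of 0.0179 and 0.0357. Both medians depended on which arrays entered. They were −0.54 and −0.32 among the 5 arrays with a low signal of Xist, an RNA of the inactive X chromosome, −2.31 and −1.17 among the 3 with a high signal, and with limma array weights −0.58 and −0.39. Both medians had the sign of that of the proximal tubule list, given above.

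Most macrophage genes had higher values in the cells from ischemic kidneys. The macrophage and monocyte list, which shares 5 genes with other lists, had a median of 0.77, with 22 of 23 measured members positive and 8 risen when adjusted over the list alone (0 over all genes tested). They included Mrc1 and Cx3cr1, given above, Fcgr1, the high-affinity IgG receptor, at 1.71 ± 0.43 (SE), and Ms4a7 at 1.63 ± 0.38. Over all alternative settings Fcgr1 ran from 0.73 to 2.06 and Ms4a7 from 0.71 to 2.13. The brightest members, Lyz2 (lysozyme) at 0.38 ± 0.23 and Tyrobp, a signalling adaptor, at 0.41 ± 0.29, did not pass. Tyrobp was at 0.087 without normal replicate 1 and 0.67 without normal replicate 3. The list mean per array was 9.74 ± 0.48 (SD, n = 5) in ischemic and 8.89 ± 0.27 (SD, n = 3) in normal arrays (exact permutation p = 0.0357). It passed limma camera (adjusted p = 2.0e-12) and not with an estimated correlation (adjusted p = 0.345 with an estimated correlation). Its median was 0.46 with arrays centred on ribosomal protein genes.

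Chemokines had a median of 0.48, with 22 of 24 positive and 2 risen when adjusted over the list alone (0 over all genes tested). These were Ccl8 at 1.89 ± 0.40 (SE) and Pf4, a chemokine of platelets and macrophages, at 1.71 ± 0.43. The brightest chemokines, Cxcl2 at 0.50 ± 0.36 and Cxcl1 at 0.99 ± 0.84, did not pass. Without normal replicate 1 they were at 0.027 and −0.15, and without normal replicate 3 at 0.78 and 1.60. Without normal replicate 2 Cxcl1 was at 1.51. The mean of the chemokine list per array had an exact permutation p of 0.0536. The chemokine list passed limma camera (adjusted p = 1.4e-05) and not with an estimated correlation (adjusted p = 0.348 with an estimated correlation). Its median was 0.90 without normal replicate 3, 0.32 among the 5 arrays with low Xist signal and 0.87 among the 3 with high signal.

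Most genes of cell division had higher values in the cells from ischemic kidneys. The G2/M and mitosis list had a median of 1.04, with 23 of 24 members positive and 6 risen when adjusted over the list alone (0 over all genes tested), among them Ube2c and Prc1. Others were Cenpe, a kinetochore motor, at 2.09 ± 0.52 (SE) and Tpx2, a spindle assembly factor, at 1.10 ± 0.34. Mki67, the proliferation marker, differed by 1.52 ± 0.53 and Ccna2 (cyclin A2) by 0.72 ± 0.34, neither past the threshold. Mki67 was at 0.77 without normal replicate 1. The list mean per array was 6.57 ± 0.45 (SD, n = 5) in ischemic and 5.48 ± 0.29 (SD, n = 3) in normal arrays, at the smallest p of the exact permutation test (0.0179). The S phase and DNA replication list had a median of 0.71, with 21 of 24 members positive and 0 past the threshold adjusted over the list alone or over all genes tested. Values were 0.49 ± 0.25 for Pcna, the replication clamp, and 0.52 ± 0.42 for Rrm1, a subunit of ribonucleotide reductase. Without normal replicate 1 they were at 0.27 and 0.33, and Rrm1 was at 0.29 without ischemic replicate 3. The macrophage list was higher in the ischemic arrays as well. In it and in both cell division lists ischemic 3 had the highest mean (10.40 for macrophage, 7.29 for G2/M and 7.71 for S phase), and ischemic 1 the lowest of the ischemic arrays (9.12, 6.18 and 6.69). That order of the ischemic arrays was not particular to these lists. It held in the fatty acid oxidation list (7.67 and 6.20) and the oxidative phosphorylation list (10.23 and 9.42), whose medians were negative. In both tubule lists ischemic 4 was the lowest. Both cell division lists passed limma camera (adjusted p = 1.2e-12 and 6.6e-07), and neither did with an estimated correlation (adjusted p = 0.243 and 0.345 with an estimated correlation). The size depended on the pseudocount. The G2/M median was 1.65 with a pseudocount of 1 and 0.60 with 64, and the S phase median was 0.45 with 64.

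Fibroblast and collagen genes, whose cell type the reporter is often used to mark, did not pass the same tests. The fibroblast list, which shares 9 genes with other lists, had a median of 0.21 over 22 members, 14 of them positive, with 0 past the threshold adjusted over the list alone or over all genes tested (limma camera adjusted p = 0.429). Of its 22 members 5 were at or above the median level of all tested genes, against 23 of 23 in the macrophage list. Most were thus dim, where the scale understates changes. The mean of the fibroblast list per array was 5.67 ± 0.39 (SD, n = 5) in ischemic and 5.57 ± 0.35 (SD, n = 3) in normal arrays (exact permutation p = 0.732). The median was 0.11 without ischemic replicate 1, 0.13 without ischemic replicate 3 or normal replicate 3 and 0.34 without normal replicate 2, and ran from 0.056 to 0.93 over all settings with a test. The highest of these, 0.93, equals the value of the single member Col1a2, so it is not read as a rise of the whole list. Col1a2, a chain of type I collagen, differed by 0.93 ± 0.73 (SE) and Thy1 by −0.011 ± 0.41. Col1a2 was at 0.24 without normal replicate 1 and 0.56 without ischemic replicate 3, and with 1 array left out Thy1 ran from −0.26 (ischemic replicate 1) to 0.34 (normal replicate 1). The collagen list, which shares 7 genes with other lists, had a median of 0.00258 over 18 members, 9 of them positive, with 0 past the threshold adjusted over the list alone or over all genes tested (limma camera adjusted p = 0.954). Its brightest members, Col4a1 of basement membranes and Col18a1, differed by −0.64 ± 0.42 and −0.97 ± 0.67, and Col4a1 was at −0.31 without normal replicate 2. The median of the collagen list changed sign with the setting, including −0.056 with arrays centred on ribosomal protein genes, −0.092 without normal replicate 1 and 0.15 without normal replicate 2.

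Among genes of collagen crosslinking and processing, 2 of 13 fell when adjusted over the list alone (0 over all genes tested). P3h2, a collagen prolyl hydroxylase, fell by 2.26 ± 0.44 (SE) and Pcolce, which enhances procollagen cleavage, fell by 2.02 ± 0.52. Over the alternative settings that measured them, P3h2 ran from −3.49 to −1.39 and Pcolce from −2.93 to −1.19. Plod3 at 0.42 ± 0.55 and P4ha1 at 0.21 ± 0.38 did not pass. With 1 array left out Plod3 ran from −0.20 (normal replicate 1) to 1.07 (normal replicate 2) and P4ha1 from −0.061 (normal replicate 2) to 0.62 (normal replicate 3). The list, with a median of −0.042 and a mean of −0.37, was not called (limma camera adjusted p = 0.276), and its median was −0.20 without normal replicate 1 and 0.19 without normal replicate 3. Among 21 paracrine growth factors, adjusted over the list alone, Egf fell as given above and Fgf1 fell by 2.18 ± 0.48 (0 over all genes tested). Igf1, a growth factor made by macrophages and mesenchymal cells, rose by 1.56 ± 0.40 over the list alone. Over all alternative settings Igf1 ran from 0.66 to 1.89 and Fgf1 from −3.51 to −1.30. Gas6 at −0.94 ± 0.46 and Grn at 0.16 ± 0.21 did not pass, with −0.56 for Gas6 without ischemic replicate 1 and 0.090 for Grn without ischemic replicate 2. That list, with a median of −0.29, was not called either (limma camera adjusted p = 0.286), and its median was 0.042 without normal replicate 3.

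Another 7 lists passed limma camera, and none of them did with an estimated correlation. Their means per array had exact permutation p values from 0.0893 (ribosomal protein) to 0.357 (lysosome), so none was under 0.05. The actin cytoskeleton list had a median of 0.29 (adjusted p = 2.99e-04, and adjusted p = 0.711 with an estimated correlation), with Tmsb4x at 0.21 ± 0.22 (SE) and Actb at 0.17 ± 0.20. Without normal replicate 1 the median was 0.11 and its adjusted p 0.196, without normal replicate 3 the median was 0.45, and over all settings with a test it ran from 0.096 to 0.46. Tmsb4x was at 0.027 and Actb at 0.088 without normal replicate 1, Tmsb4x at 0.33 without normal replicate 3 and Actb at 0.11 without ischemic replicate 3. The ribosomal protein list had a median of 0.19 (adjusted p = 0.00735, and adjusted p = 0.598 with an estimated correlation), with Rps14 at 0.048 ± 0.17 and Rps3 at 0.015 ± 0.18, both of which turn negative when arrays are centred on this list. With 1 array left out Rps3 ran from −0.045 (normal replicate 2) to 0.055 (normal replicate 1). Without normal replicate 2 the limma camera adjusted p of the ribosomal protein list was 0.134. Over all 23 settings with a test that list lost the call in 6, with a highest limma camera adjusted p of 0.289, and its median ran from 0.0080 to 0.30. In these 2 lists 0 members passed adjusted over the list alone or over all genes tested. The oxidative stress and iron list had a median of −0.41 (adjusted p = 0.00295, and adjusted p = 0.514 with an estimated correlation). Gpx3, the plasma glutathione peroxidase made by the proximal tubule, fell by 1.68 ± 0.39 as the 1 member past the threshold adjusted over the list alone (0 over all genes tested). Sod1 at −0.46 ± 0.21 and Fth1 at −0.21 ± 0.18 did not pass. Its median was −0.24 without normal replicate 1, −0.26 with an adjusted p of 0.0657 with array weights, and −0.081 with an adjusted p of 0.516 among the 5 arrays with low Xist signal.

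The endothelial list had a median of −1.06 (limma camera adjusted p = 0.00499, and adjusted p = 0.711 with an estimated correlation), with Tek, the angiopoietin receptor, at −1.49 ± 1.06 (SE) and Cdh5, VE-cadherin, at −1.03 ± 0.99. Its adjusted p was 0.0751 without ischemic replicate 1, 0.0605 without ischemic replicate 2, 0.0541 without normal replicate 2 and 0.203 without normal replicate 3. Its median was −0.62 without ischemic replicate 1 and ran from −2.06 to −0.55 over all settings with a test. Without ischemic replicate 1 Tek was at −0.73 and Cdh5 at −0.45, and Cdh5 was at −1.71 without normal replicate 1 and −0.69 without normal replicate 3. The list of alternatively activated macrophages had a median of 0.23 (adjusted p = 0.0131, and adjusted p = 0.711 with an estimated correlation), with Fcrls and Mrc1 risen when adjusted over the list alone (0 over all genes tested) and Tgm2 at −0.44 ± 0.34. Its median was −0.18 without ischemic replicate 3 and −0.041 without normal replicate 1, and 0.44, 0.41 and 0.60 without ischemic replicate 1, ischemic replicate 4 and normal replicate 2. Tgm2 was at −0.27 without ischemic replicate 1. The interferon response list had a median of 0.39 (adjusted p = 0.0265, and adjusted p = 0.711 with an estimated correlation), with Oas1a at 1.10 ± 0.37 and Rsad2 at −0.44 ± 0.51. With 1 array left out Rsad2 ran from −0.72 (ischemic replicate 5) to −0.14 (normal replicate 3). The list lost the call without ischemic replicate 3, 4 or 5 (adjusted p = 0.0717, 0.0858 and 0.174) or normal replicate 1 (0.306, with a median of 0.16). Over all 23 settings with a test the interferon list lost the call in 6, with a highest limma camera adjusted p of 0.469. The lysosome and phagocytosis list had a median of 0.15 (adjusted p = 0.0493, and adjusted p = 0.711 with an estimated correlation), with Grn at 0.16 ± 0.21 and Psap at 0.14 ± 0.22. Psap was at 0.0030 without normal replicate 1, 0.074 without ischemic replicate 3 and 0.22 without ischemic replicate 1, and Grn at 0.090 without ischemic replicate 2. The list lost the call without ischemic replicate 2, 3, 4 or 5 (adjusted p = 0.0603, 0.479, 0.0501 and 0.0847) or normal replicate 1 (0.306), and its median was 0.23 without ischemic replicate 1 and 0.084 without ischemic replicate 3. Over all 23 settings with a test the lysosome list lost the call in 12. In the endothelial, interferon and lysosome lists 0 members passed adjusted over the list alone or over all genes tested.

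The other 21 lists were not called by limma camera, with adjusted p from 0.0532 to 0.991. Their medians and adjusted p are given in brackets. Those with the lowest p were NF-kappaB feedback and targets (0.34, 0.0532), B cell (0.59, 0.0908), unfolded protein and heat shock (0.065, 0.193), matrix glycoproteins and proteoglycans (−0.54, 0.193), TGF-beta signalling (0.27, 0.206), complement (0.068, 0.228) and immediate early genes (0.14, 0.240). Next were dendritic cell and antigen presentation (0.16, 0.287), hypoxia (−0.047, 0.334), cytokines (0.14, 0.334), neutrophil (0.19, 0.342), podocyte (−0.29, 0.426), Wnt pathway (−0.066, 0.426) and erythroid and platelet (−0.19, 0.426). The others were p53 and growth arrest (−0.049, 0.519), matrix proteases and their inhibitors (0.36, 0.620), tubular injury (−0.063, 0.620), T and NK cell (0.0017, 0.620), glycolysis (0.13, 0.699), smooth muscle and myofibroblast (0.20, 0.942) and pericyte and mesangial (0.074, 0.991). In the smooth muscle list the median was 0.20 and the mean −0.015, with camera's direction down. In the pericyte list the median was 0.074 and the mean −0.034, with camera's direction up. In the erythroid and platelet list, adjusted over the list alone, Pf4 rose (0 over all genes tested). Slc4a1, the anion exchanger of red cells and of the collecting duct, fell by 1.50 ± 0.36 (SE) in the same adjustment. In the other 20 of these lists 0 members passed adjusted over the list alone or over all genes tested.

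The labels give every mouse as male, and the arrays differed in genes tied to sex. Xist, the RNA that coats the inactive X chromosome of females, had a value of 11.21 in ischemic 1, 9.39 in ischemic 2 and 11.01 in normal 1 on its brightest probe set, and between 4.49 and 4.96 on the 5 other arrays. The mean of 9 probe sets of the Y-linked genes Eif2s3y, Kdm5d and Uty was 5.44 in ischemic 1 and 5.15 in normal 1, and between 6.05 and 6.38 on the 6 other arrays, including 6.33 in ischemic 2. In ischemic 1 and normal 1, 7 of the 9 lay below all 5 arrays of low Xist signal, but 1 Kdm5d probe set was at 8.53 in ischemic 1, against 5.11 to 6.62 on the 7 other arrays. The other Kdm5d probe sets were at 4.53 and 6.86 in ischemic 1, below all 5 arrays of low Xist signal. With Xist signal as a block, chosen after seeing the data, limma called 1 gene, Sugct. Camera called 17 lists, against 15 without it. Within the 5 arrays of low signal (3 ischemic, 2 normal) limma called 0 genes, with 973 at an unadjusted p under 0.05, and camera called 14 lists. For the 3 of high signal (2 ischemic, 1 normal) only values are given here, since a lone normal array has no spread of its own to test. The median of the proximal tubule list was −3.26 with the block, −3.03 in the first set and −3.63 in the other, and that of the macrophage list was 0.81, 0.73 and 0.99.

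**Figure D3:**
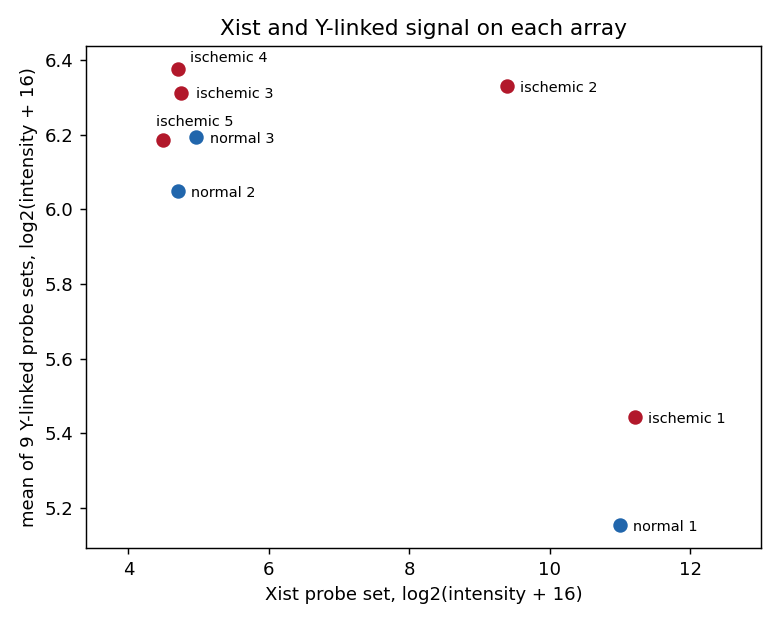
Signal of the brightest Xist probe set against the mean of 9 Y-linked probe sets on each array, both as log2(intensity + 16) (red, ischemic; blue, normal; axes do not start at 0). Ischemic 1 and normal 1 have high Xist and low Y-linked signal, ischemic 2 is high in both at 9.39 and 6.33, and the 5 other arrays have low Xist signal.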

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

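The tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the arrays. Of 126 values per group of 5 ischemic arrays (named genes, list means, quality measures), 3 had 1 array far from the others by Dixon's criterion at 0.71, where chance gives about 6.3. The median correlation of ischemic 1 with the other arrays was 0.753, against 0.890 to 0.903 for the other 4. Gas6 was 7.30 in ischemic 1, against 9.11 to 9.28 in the other 4. Wfdc15b was 6.37 in ischemic 2, against 5.69 to 5.88 in the other 4.

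Tubule lists were lower and the macrophage list higher in the ischemic arrays, and the division of the arrays by Xist signal does not account for the fall of the proximal tubule list, whose median stayed at −3.03 or lower both with that division as a block and among the 5 arrays of low signal. A common fall of tubule RNA carried into the sort would lower both tubule lists by a common factor. Over bright members the proximal list fell further than the distal list by −1.01 (two-sided exact permutation p = 0.0893). This difference cannot decide the question, since the scale understates the change of dim genes. The distal list was dimmer, at 7.93 against 9.86 in normal arrays over all members, and holds Wnk1, which is also expressed widely. The explanation stays open. A lower share of tubule RNA would raise the markers of the other cell types alike. The macrophage list rose by 0.85 over bright members, where the median of 9 other cell lists was 0.044 (SD between lists 0.47). This gap of 0.80 goes against that explanation but is weak evidence. The macrophage list held 23 bright members, against 3 neutrophil, 4 pericyte, 5 fibroblast and 5 podocyte members. The remaining lists held 6 (B cell) to 16 (endothelial). The scale understates changes of dim genes here too. The explanation was not settled, since another list rose more than the macrophage list without ischemic 3, ischemic 5 or normal 1. The highest other list rose by 0.91, 1.03 and 1.05 there, against 0.68, 0.91 and 0.69. The gap to the median still exceeded the SD between lists there (0.59 against 0.56, 0.88 against 0.73 and 0.89 against 0.79). With all arrays the highest other list was the B cell list (0.66), whose mean was highest in the arrays of high Xist signal. The macrophage gain of 0.88 over the mean of 10 lists had a two-sided exact permutation p of 0.0536. A response of the cells or of the cell mixture to ischemia may contribute, as a hypothesis that these arrays cannot separate from both.

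Xist signal was high in 3 arrays labelled male. A single unspecific probe set is excluded, since every Xist probe set was higher in those 3 arrays than in the 5 others by at least 1.13. RNA of females alone may account for normal 1, whose Y-linked mean differed by −0.89 from the lowest of the 5 other arrays (SD of those 5, 0.13), with 7 of 9 probe sets below and 0 above all 5. For ischemic 1 it stays open, since the mean differed by −0.60 with 7 of 9 below, but a Kdm5d probe set was at 8.53, above the 5.11 to 6.62 of all other arrays. What goes against it rests on that single probe set. The other Kdm5d probe sets, at 4.53 and 6.86 in ischemic 1, lay below all 5. RNA of females alone cannot account for ischemic 2, whose Y-linked mean lay 0.28 above that lowest value, so that a mixture of both sexes there stays a hypothesis. No biological explanation beyond the sex of the RNA was tested, since the design has no group by sex.

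Normal 3 was closer to ischemic 5 (r = 0.976) and ischemic 3 (r = 0.950) than to any normal array (r = 0.923 at most). Each array was placed between the means of the other ischemic arrays (0) and the other normal arrays (1) on the 100 genes of lowest limma p chosen without it, and normal 3, at 0.39, lay 0.062 above the highest ischemic array, where the SD of the ischemic arrays was 0.27. This placement does not exclude an ischemic sample with a normal label. Normal 3 lay above the highest ischemic array in the proximal tubule list mean (8.97 against 7.78) and the distal nephron list mean (7.87 against 6.67). On the distal list it matched normal 1 (7.87), where the SD of the ischemic arrays was 0.25. Both lists were set before the data were examined and kept their camera call without normal 3. Their values thus go against a wrong label, for these 2 lists. With the correlations and the placement on the other side, the question stays open. The deviations of normal 3 and ischemic 5 from their group means correlated at 0.31, the highest of the 15 pairs across groups, the next being 0.18. A shared handling batch could give this, and it cannot be told apart from chance because no label names a batch.

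The limma count at an adjusted p of 0.05 was 0, which all 56 of the 56 splits reach by construction, so the splits decide nothing about it (the highest other gave 1). Chance could not be excluded for the counts that follow. The 1297 genes at an unadjusted p under 0.05 were reached by 8 of 56 splits, with 2829 as the highest other. The 15 lists called by camera were reached by 16 of 56 splits, with 20 as the highest other. The split that follows Xist signal gave 2724 genes at an unadjusted p under 0.05 and 15 lists, so the arrays hold a structure other than ischemia, and with Xist signal as a block the comparison of ischemic and normal arrays gave 17 lists.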

How the results depend on the processing

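The settings with Xist signal, an adjusted p under 0.1 and the permutation of list means were chosen after the results were seen. Of the 15 called lists, 8 kept call and direction under all 23 other settings with camera's preset correlation and more than 1 array per group. These were proximal tubule (median −3.76 to −2.42), distal nephron (−2.26 to −1.17), fatty acid oxidation (−1.46 to −0.54), oxidative phosphorylation (−0.93 to −0.32), G2/M (0.60 to 1.65), S phase (0.45 to 0.99), macrophage (0.46 to 0.92) and chemokines (0.32 to 0.90). The count of 15 lists became 1 with an estimated correlation, 2 with fry and 7 by exact permutation of list means (unadjusted p), and lay between 13 and 18 otherwise. The count of 0 genes became 216 with arrays centred on ribosomal protein genes, 31 with an intensity trend, 15 above the 40th percentile of brightness (0 above the 60th), 5 with array weights (Slc22a30, Wfdc15b, Sugct, Dnase1 and Kng1), 3 at an adjusted p under 0.1 (Sugct, Slc22a30 and Wfdc15b), 2 with the mean of probe sets (Slc22a30 and Wfdc15b), 1 with a pseudocount of 1 (Sugct) and 1 with the Xist block (Sugct). Leaving out 1 array gave 0 to 113, the latter without normal replicate 3. The collagen median turned to −0.056 with ribosomal centring, −0.065 with a pseudocount of 1, −0.075 and −0.56 above the 40th and 60th percentiles, −0.050 with probe sets tested singly, and −0.092 to 0.15 with 1 array left out. Reversals elsewhere were Rps14 −0.036, Rps3 −0.068 and P4ha1 −0.039 with ribosomal centring, Thy1 0.26 and P4ha1 −0.050 with the replicate block, Tgm2 0.0086 and Plod3 −0.043 among 5 arrays of low Xist signal, Rps3 −0.14 and collagen crosslinking 0.22 among the 3 of high signal, and collagen crosslinking 0.00071 with array weights. With 1 array left out, values spanned −0.19 to 0.016 for Wnk1, −0.15 to 1.60 for Cxcl1, −0.045 to 0.055 for Rps3, −0.26 to 0.34 for Thy1, −0.20 to 1.07 for Plod3, −0.061 to 0.62 for P4ha1, −0.18 to 0.60 for alternatively activated macrophages, −0.20 to 0.19 for collagen crosslinking, −0.25 to 0.042 for paracrine growth factors and −0.056 to 0.043 for the difference of array medians. S100a4 stayed between 0.19 and 0.53 and never passed. Of the 21 lists not described singly, 9 were called in at least 1 of these 23 settings (28 of 483 values) and 18 changed sign in at least 1, never together with a call. The cause was not tested for these changes. Groups share replicate numbers 1 to 3, whose deviations correlated at 0.16, −0.088 and 0.10. These are too few pairs to tell whether the numbers pair the samples. The deviations of ischemic 2 correlated at 0.18 with those of normal 1, which also had a high Xist signal, and at −0.088 with those of normal 2. With the replicate block limma called 0 genes (1406 at an unadjusted p under 0.05) and camera 17 lists. Dim genes lie near the floor, where signal over background limits what can be seen.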

Other observations

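The test named in this part was chosen after the results were seen. Lymphocyte genes followed individual arrays and not the groups. The mean of the B cell list was 8.90 in ischemic 1, 7.26 in ischemic 2 and 6.66 in normal 1, and between 5.40 and 5.80 on the 5 other arrays. The T and NK cell list was at 7.23, 6.16 and 6.81 in the same arrays, and between 5.26 and 6.01 on the others. These are the 3 arrays with a high Xist signal. The endothelial list ran from 6.07 in ischemic 1 to 9.55 in ischemic 5, with 7.53 to 9.04 in normal arrays, the widest range over the ischemic arrays of the 40 lists apart from B cells.

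In cells sorted on an FSP1 reporter, the macrophage list passed limma camera with the preset correlation and not with an estimated one (adjusted p = 0.345 with an estimated correlation). The fibroblast and collagen lists did not pass with either, and the difference between these lists was not tested. Most members of the fibroblast list were dim, where the scale understates changes. S100a4 is known to be expressed by macrophages as well as fibroblasts, so a larger share of macrophages among the GFP-positive cells may underlie part of the difference, as a hypothesis. Over bright members the macrophage list rose by 0.80 more than the median of 9 other cell lists, and over all members its gain on the mean of 10 lists was 0.88 (two-sided exact permutation p = 0.0536), which leaves it open. Lyz2, the brightest gene of that list, was at 12.57 ± 0.24 (SD, n = 5) in ischemic and 12.19 ± 0.26 (SD, n = 3) in normal arrays, and 5 genes of the list are held by other lists. No marker or morphology of single cells was analysed here that would decide it.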
